A study of Mus musculus with 12 samples.

How the data were processed

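Gene expression was measured with Illumina bead arrays in 12 samples of mouse epiblast, taken at E7.75. The labels give 4 groups of 3 arrays: control anterior, control posterior, knockout anterior and knockout posterior, where control is Dkk+/+ and knockout is Dkk-/-. The protocol in the labels speaks of 4 genotypes but names only these, and what the others were is not given in the sources used here. RNA was extracted with microcolumns, labelled with biotin by the standard Illumina procedure and read with GenomeStudio, per the labels' protocols and the submitters' processing notes. The GenomeStudio version, the array model and the scanner are not given in the sources used here.

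The deposited table of non-normalized values holds probe signal intensity on a linear scale for 46237 probes, with no background subtraction and no scaling between arrays, per the file headers and its values. Beside each intensity it holds a detection p-value, per the file headers, which ranks the signal among the negative control probes of the same array. These p-values are multiples of 0.00107, which corresponds to 936 negative controls. The deposited series matrix holds log2 values for 33557 of the probes (72.6%). Every array had a median of 6.66 and kept the rank order of its signals (Spearman 1). Quantile normalization would give this, but so would median scaling, and these values do not show whether background was subtracted. The software of that normalization is not given in the sources used here. The series matrix was used only as an alternative.

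For the comparisons, the intensities were background corrected, quantile normalized and log2 transformed with neqc in limma 3.58.1 (R 4.3.3), with an offset of 16 and the negative controls implied by the detection p-values. Probes with a detection p-value under 0.05 on at least 3 of the 12 arrays were kept, which left 21051. Gene names came from the probe table of the series matrix and were updated through the RefSeq gene table of assembly GRCm38.p6, which was used only for names and for the order of genes along a chromosome. Of the probes, 30058 carried 1 gene name (25561 matched by gene number, 1936 by accession, 2561 kept the name in the probe table), 643 names were updated, and 16179 probes had no name in the sources used here and were left out. Of the detected probes, 15924 had a name. Where a gene had several detected probes (3455 genes), the probe with the highest mean was used, which gave 11124 genes.

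A linear model with 4 group means was fitted to each gene with limma, with moderated variances (prior degrees of freedom 4.86). 6 contrasts were tested: knockout against control in the anterior region, in the posterior region and on average over both regions, posterior against anterior in control and in knockout arrays, and the interaction, which is the posterior genotype effect minus the anterior one. Genes with a Benjamini-Hochberg adjusted p under 0.05 in a contrast were called. Adjusted p-values below are limma's unless another test is named. The labels do not state which arrays share embryos, so p-values measure only the spread between these samples. Changes are log2 fold changes with their standard error (SE), and levels are log2 normalized intensities with the standard deviation (SD) over 3 arrays. Where no array of a group detected the gene, the fold is given as a lower bound, computed with that group's arrays raised to their lowest detected signal. The number of arrays limits the precision.

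Gene lists were written before the data were examined: Wnt/beta-catenin target genes, Wnt ligands and receptors, secreted and membrane Wnt antagonists, forebrain and anterior neural plate, midbrain and hindbrain, primitive streak, paraxial and presomitic mesoderm, Hox genes, epiblast pluripotency, early neural differentiation, BMP and TGF-beta signalling, FGF/ERK signalling, retinoic acid pathway, cell cycle, apoptosis and p53 targets, glycolysis and hypoxia, immediate-early and stress genes, mitochondrial-encoded and ribosomal protein genes, X-inactivation and Y-linked genes, visceral endoderm, anterior visceral endoderm and prechordal plate, definitive endoderm and foregut, node and notochord, cardiac and anterior mesoderm, extraembryonic and lateral mesoderm, blood and endothelium, extraembryonic ectoderm and trophoblast, surface ectoderm and amnion, neural crest, and primordial germ cells. Several genes belong to more than 1 list. The 29 lists other than the X and Y genes were tested with camera in limma, with a preset correlation of 0.01 and adjustment over the lists within each of 4 contrasts, beside a run with an estimated correlation. The one-way test of limma's fry was used where a single list is discussed without comparison to other genes.

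The genes named were set by a rule fixed before the data were examined. It names Dkk1; in each contrast the 12 largest rises and 12 largest falls among genes past the threshold whose arrays did not overlap between the groups (within each region for the average); the 10 smallest p-values where fewer than 10 genes passed; up to 4 members of each list discussed; and T, Otx2, Six3, Hesx1, Lhx5, Axin2, Lef1, Sp5, Cer1, Gsc, Foxa2, Wnt3, Wnt3a, Fgf8, Cdx1, Cdx2, Pou5f1 and Xist. T has no probe in the gene table and the Six3 probe was not detected on enough arrays. Genes without a proper symbol were passed over: 1 in the posterior contrast, 1 in the average and 1 in the knockout axis.

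The position of the anterior knockout arrays along the control axis was the slope, across genes, of the anterior genotype change on the control difference between regions. It was computed so that no array entered both sides. The fit and its threshold were tested on simulated data built from the real means and spreads of 11124 genes, with 200 genes changed in each of 10 runs. The simulated genes were independent and had the same spread in all groups. Background correction, normalization, the detection filter and the choice of probes were not tested in this way. For the anterior genotype contrast the fit recovered 26.7% of 1.5-fold changes, 74.9% of 2-fold changes and 98.3% of 4-fold changes, with 6.5% false calls. For the posterior genotype contrast the shares were 29%, 72.7% and 98.5%, with 4% false calls. A slope of 0.2 put into the simulation was returned as 0.202, and as 0.267 when arrays were shared.

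Alternatives planned before the data were examined were no background correction, an offset of 50, cyclic loess, median scaling, the series matrix, no filter, a filter at detection p under 0.01 on at least 6 arrays, probes tested singly or averaged, only the arrays of the groups compared, trended and robust variances, array weights, a minimum of 1.5-fold, replicate blocks, an estimated correlation for the lists, and leaving out each array in turn. Added after the data were seen were median scaling over the 13883 probes detected on all arrays and Xist as a covariate. Figures were drawn with matplotlib 3.10.9.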

Results

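Expression was profiled in the epiblast, the embryonic layer that forms the body, of mouse embryos collected at E7.75. Each epiblast was dissected into an anterior part, from which the head arises, and a posterior part, which holds the primitive streak. Control (Dkk+/+) and knockout (Dkk-/-) tissue of each region was measured on 3 arrays, 12 in all. The sample codes name Dkk1, which encodes a secreted inhibitor of Wnt signalling. The mean signal per array ran from 189 in knockout posterior replicate 2, with 301 as the next lowest, to 693 in control anterior replicate 2. Between 36.2% and 42.3% of the 46237 probes were detected per array, and 11124 genes were compared. The median SD of a gene within a group was 0.17 in control anterior, 0.158 in control posterior, 0.186 in knockout anterior and 0.202 in knockout posterior arrays, on the log2 scale.

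Dkk1 itself was not lower in the anterior arrays labelled knockout. Its level was 5.98 ± 0.17 (SD, n = 3) in control anterior arrays (6.1, 5.78 and 6.06) and 6.14 ± 0.14 (SD, n = 3) in knockout anterior arrays (6, 6.27 and 6.17), a change of 0.17 (SE 0.17) with an adjusted p of 0.83. In the posterior region the levels were 5.05, 5.12 and 4.64 in control and 4.74, 4.31 and 4.46 in knockout arrays, where no array detected the probe. No fold is given for the posterior region, since control arrays did not lie above the lowest detected signal of the knockout arrays on average (adjusted p = 0.44). Dkk1 was lower in the posterior than in the anterior region of control arrays, with a change of -1.04 (SE 0.17, adjusted p = 0.0021), and at least 2.26-fold lower in knockout arrays (adjusted p = 4.5e-05). The place of this single probe relative to the deleted part of the gene is not given in the sources used here, so the signal cannot check the genotype labels. "Knockout" below therefore means the arrays labelled so, and each direction between genotypes rests on those labels.

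**Figure D1:**
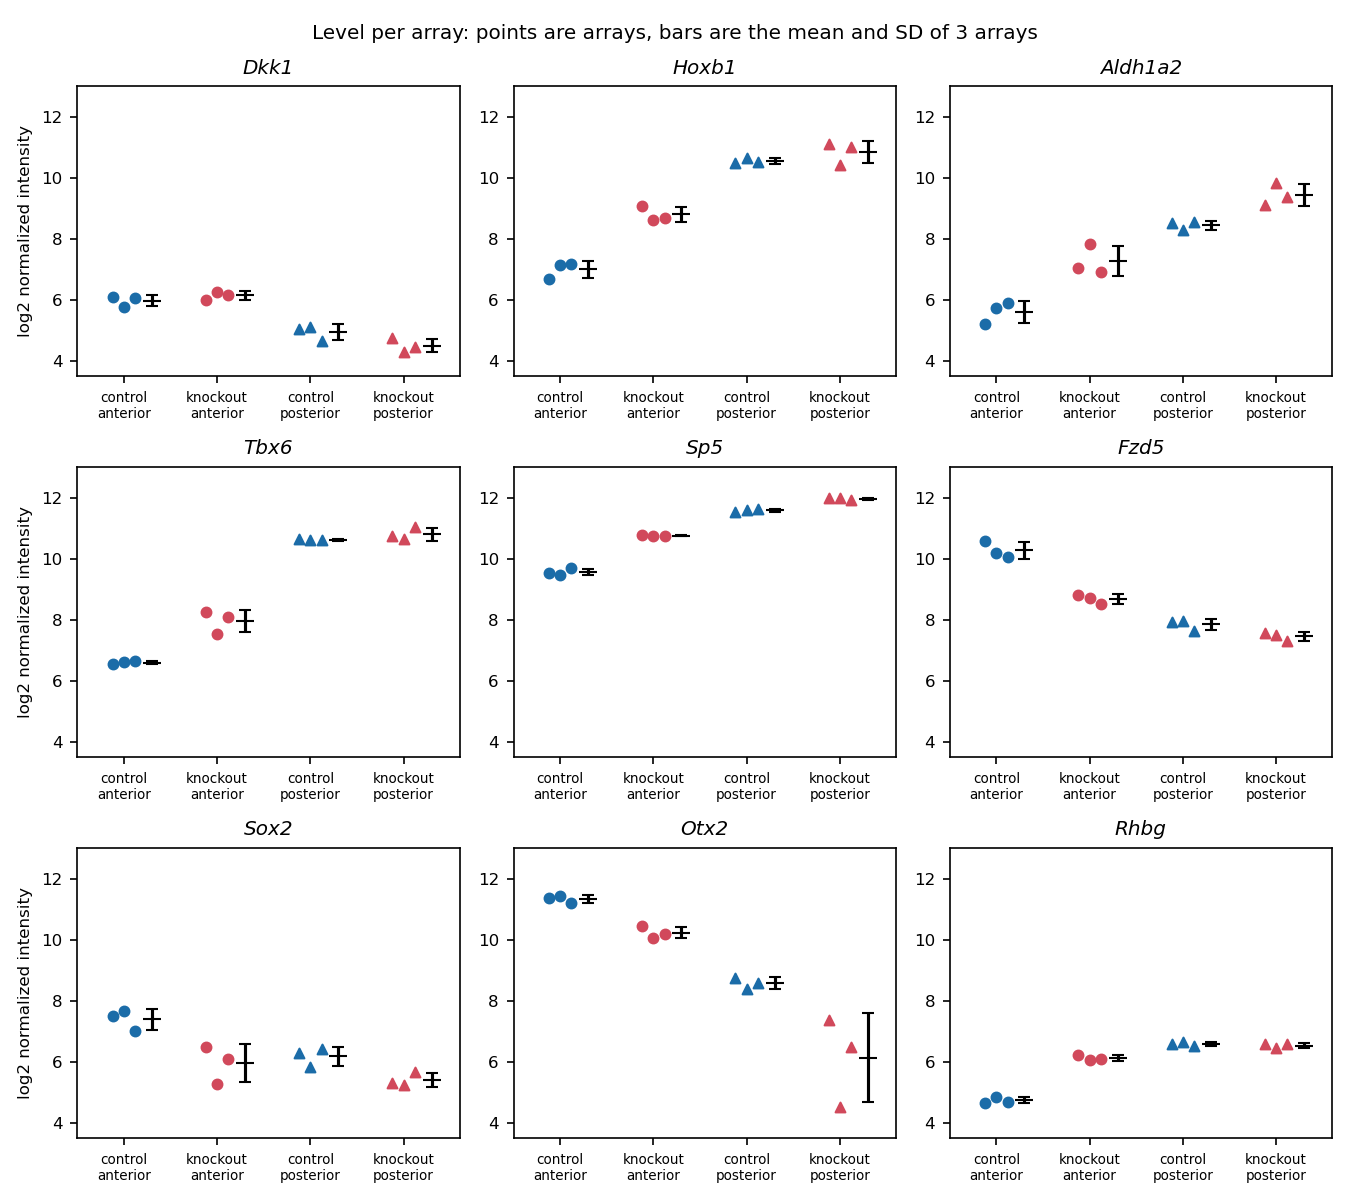
Levels of 9 genes on each of the 12 arrays (y axis, log2 normalized intensity), by genotype and region; points are arrays and bars the mean and SD of 3 arrays. Dkk1 lay at 5.98 in control and 6.14 in knockout anterior arrays, while Hoxb1, Aldh1a2, Tbx6, Sp5 and Rhbg were higher and Fzd5 and Sox2 lower in the anterior knockout arrays.

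The first comparison asked how the anterior epiblast differs between the genotypes. Several genes of the paraxial mesoderm and the primitive streak and several Wnt targets were higher in the anterior arrays labelled knockout. Hoxb1, a Hox gene of the hindbrain that responds to retinoic acid, rose by 1.79 (SE 0.2, adjusted p = 0.0018), from 7 ± 0.27 to 8.79 ± 0.25 (SD, n = 3). Aldh1a2, which makes retinoic acid, rose by 1.66 (SE 0.26, adjusted p = 0.015), and Tbx6, a T-box factor of the presomitic mesoderm, by 1.36 (SE 0.17, adjusted p = 0.0045; its other probe by 0.41). The direct Wnt targets Sp5 (1.19, SE 0.11, adjusted p = 0.00047) and Axin2 (0.65, SE 0.12, adjusted p = 0.032) rose as well. Several genes of the anterior neural plate were lower. The Wnt receptor gene Fzd5 fell by 1.6 (SE 0.16, adjusted p = 0.00088). Sox2, a factor of pluripotent and neural cells, fell by 1.44 (SE 0.28, adjusted p = 0.045), though by its other probe the change was only -0.17, and Lhx5, a LIM homeobox gene of the forebrain, fell by 1.21 (SE 0.18, adjusted p = 0.013).

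The other genes with large rises were Myl2 (1.59), a myosin light chain of the heart, Ripply2 (1.58), a repressor in somite formation, Igfbpl1 (1.54), Gna14 (1.5), and Tbx1 (1.48), a T-box factor of pharyngeal mesoderm. Foxc2 (1.46), a forkhead factor of paraxial mesoderm, the Wnt ligands Wnt2 (1.45) and Wnt8a (1.32), and Rhbg (1.38), an ammonium transporter, rose too. Their adjusted p-values lay between 0.00029 for Rhbg and 0.032 for Wnt2. Among the large falls were Dynlrb2 (-1.86), a dynein light chain, Dppa4 (-1.79), a pluripotency-associated gene, Hdc (-1.54), the histidine decarboxylase, and Dlx6 (-1.33). Gsc (-1.24), a homeobox gene of the organizer and prechordal plate, Shisa2 (-1.21), an antagonist of Wnt and FGF receptors, and Pou3f1 (-1.09), a POU factor of neural progenitors, were lower as well. Their adjusted p-values lay between 0.0045 for Shisa2 and 0.048 for Dppa4. Rhox9 was at least 1.49-fold lower (adjusted p = 0.015) and Odf3b at least 1.99-fold lower (adjusted p = 0.023), since no knockout anterior array detected either, and the other Odf3b probe changed by only -0.11. Other probes also changed less for Fzd5 (-0.79), Hdc (-0.76) and Shisa2 (-0.54). Only some arrays of a group detected Ripply2 (2 of 3 control), Rhbg (1 of 3 control), Dynlrb2 and Dlx6 (2 of 3 knockout).

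Of the genes fixed in advance, Otx2, a homeobox gene required for the forebrain, was 11.33 ± 0.12 in control and 10.23 ± 0.19 in knockout anterior arrays (SD, n = 3). All 3 knockout arrays lay below the 3 controls, but the change of -1.1 did not pass (SE 0.49, adjusted p = 0.53). The error includes the SD of 1.45 among knockout posterior arrays, and fitted on the anterior arrays alone its adjusted p was 0.03. Hesx1 (-0.9, adjusted p = 0.2; detected on 1 of 3 knockout arrays), Fgf8 (0.93, adjusted p = 0.06), and Cdx2 (0.71, adjusted p = 0.08) did not pass. Values for Cdx1 (1.02, adjusted p = 0.48), Wnt3a (0.67, adjusted p = 0.41), Lef1 (0.41, adjusted p = 0.57) and Pou5f1 (-0.36, adjusted p = 0.61) lay further from the threshold. Nor did Cer1 (0.28, adjusted p = 0.78), Foxa2 (0.16, adjusted p = 0.9) and Xist (2.31, adjusted p = 0.61; detected on 2 of 3 control arrays), and Wnt3 was not detected on any anterior array.

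Grouped by list, 6 of 17 genes of the paraxial and presomitic mesoderm rose, none fell and 11 did not pass; the median change was 0.93, and 12 rose when adjusted over the list alone. Dll1 (1.01), a ligand of Notch signalling, was among them. In the primitive streak list 5 of 24 genes rose, among them Fst (1.2) and Ifitm1 (0.79), 1 fell (Gsc) and 18 did not pass, with a median of 0.57; adjusted over the list alone, 12 rose and 1 fell. The Wnt/beta-catenin targets had 4 of 25 genes higher, none lower and 21 not past, with a median of 0.41, and 11 higher adjusted over the list alone. Of 15 forebrain and anterior neural plate genes 4 fell, none rose and 11 did not pass, with a median of -0.77; adjusted over the list alone, 8 fell. By camera the adjusted p was 4.9e-18 for paraxial mesoderm, 2.6e-10 for the streak, 1.9e-10 for Wnt targets and 7e-11 for the forebrain. These 4 calls held with an estimated correlation (adjusted p of 3e-04, 0.0029, 0.0012 and 0.018). They are not independent, since the lists share genes. Of the Wnt targets that rose, Tbx6 and Dll1 also belong to the paraxial mesoderm list, and Sp5 and Dll1 to the primitive streak list.

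A further 9 lists passed camera with the preset correlation only. In the retinoic acid pathway 4 of 14 genes rose, among them Meis1 (0.99) and Crabp1 (1.03), with an adjusted p = 0.12 with an estimated correlation. Cardiac and anterior mesoderm had 1 of 20 genes higher, Tbx1 (adjusted p = 0.12 with an estimated correlation). Midbrain and hindbrain had 2 of 15 higher, Hoxb1 and Gbx2, the latter by 1.02 (adjusted p = 0.084 with an estimated correlation). Of the Hox genes 1 of 22 rose, Hoxb1, with a median of 0.03 (adjusted p = 0.23 with an estimated correlation). Epiblast pluripotency had 3 of 17 genes lower, with Slc7a3 at -0.91, a transporter gene whose other probe differed in sign (adjusted p = 0.084 with an estimated correlation). Anterior visceral endoderm and prechordal plate had 3 of 11 lower, Gsc, Shisa2 and Fzd5 (adjusted p = 0.084 with an estimated correlation). Node and notochord had 1 of 16 lower, Dynlrb2 (adjusted p = 0.19 with an estimated correlation). Extraembryonic ectoderm and trophoblast had 1 of 20 lower, Rhox9, while Elf5 at -2.01, detected on 1 of 3 knockout arrays and with its other probe at -0.68, had an adjusted p of 0.052 (list adjusted p = 0.13 with an estimated correlation). Among primordial germ cell genes 1 of 11 fell, Sox2, and 1 rose, Ifitm1 (adjusted p = 0.12 with an estimated correlation).

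The remaining 16 lists did not pass. Median changes were 0.13 for Wnt ligands and receptors (4 rose and Fzd5 fell of 29; Wnt5a rose by 0.98, its other probe by 0.41), 0.23 for secreted and membrane Wnt antagonists (Frzb rose by 1.12 and Shisa2 fell), 0.09 for BMP and TGF-beta signalling and 0.1 for FGF/ERK signalling. They were -0.06 for the cell cycle, -0.11 for apoptosis and p53 targets, -0.09 for glycolysis and hypoxia and -0.04 for immediate-early and stress genes. Among markers of other tissues the medians were -0.05 for visceral endoderm, -0.03 for definitive endoderm and foregut, -0.03 for extraembryonic and lateral mesoderm, -0.02 for surface ectoderm and amnion (Dlx6 fell) and -0.08 for the neural crest (Twist1 rose by 1.19). Early neural differentiation had a median of 0.04 with a mean of -0.14 and a downward test. Mitochondrial-encoded and ribosomal protein genes and blood and endothelium both had a median of -0.02, a mean of 0 and a downward test. The X-inactivation and Y-linked genes, not tested as a set, had a median of -0.4 and a mean of 0.03 over 4 genes, none of them past the threshold.

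In all, limma called 36 genes higher and 20 lower in the anterior knockout arrays (56 genes), and 1009 had an unadjusted p under 0.05, where 556 would be expected by chance. The arrays of the 2 groups did not overlap for any of the 56 (10% by chance for a gene not chosen by its test), which their selection on the same arrays largely fixes. Named genes lost their call in 1 to 17 of up to 25 other settings, most often Sox2 (17), Dynlrb2 (16), Dppa4 (15), Frzb (15), Meis1 (14), Crabp1 (14), Axin2 (13) and Odf3b (13). Unless stated, counts of lost calls leave out the settings with replicate blocks. Array weights gave 542 genes (239 higher and 303 lower), an offset of 50 gave 93, trended and robust variances 87, no filter 36, only the groups compared 27 and Xist as a covariate 18. The series matrix gave 43 higher and 39 lower, median scaling over the probes detected on all arrays gave 17 higher and 4 lower, and median scaling over all probes, which shifted the median of all genes by -0.22, gave 0. Without 1 array the count was 27 (control anterior replicate 1), 17 (control anterior replicate 2), 31 (control anterior replicate 3), 35 (control posterior replicate 3), 24 (knockout anterior replicate 1) or 25 (knockout anterior replicate 2).

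**Figure D2:**
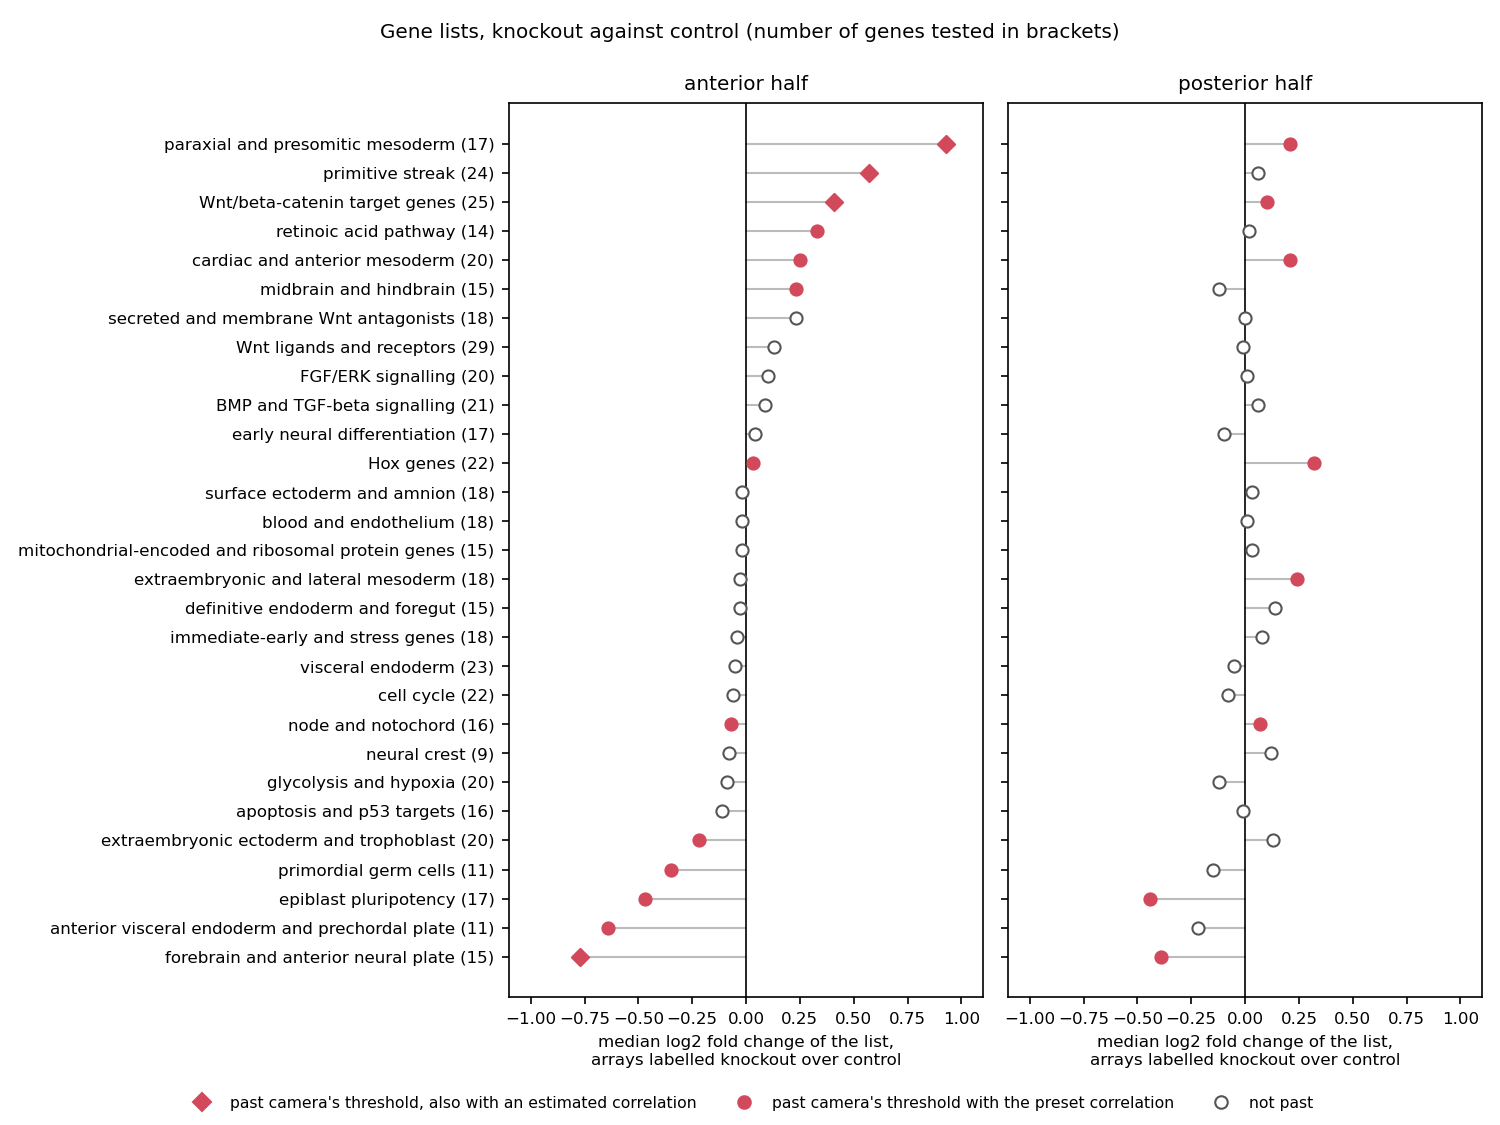
Median log2 fold change of each gene list, knockout over control (x axis), in the anterior region (left) and the posterior region (right), with the number of genes tested in brackets. Filled symbols passed camera, and diamonds passed with an estimated correlation too: paraxial mesoderm (0.93), primitive streak (0.57), Wnt targets (0.41) and forebrain (-0.77) in the anterior region, none in the posterior region.

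In the posterior region the same comparison called no gene. The smallest adjusted p belonged to Slc7a3, a transporter of cationic amino acids, at -1.16 (SE 0.15, adjusted p = 0.051), with its other probe at 0.15. Slc7a3 passed in 14 of 27 other settings, and Irx3 and Otx2 passed in 7 each. Irx3, an Iroquois homeobox gene of neural tissue, followed with -1.17 (SE 0.18, adjusted p = 0.077) and Arid5b, a chromatin factor, with -0.87 (SE 0.14, adjusted p = 0.077). The others among the 10 smallest p-values were Lypd2 (1.58), Usp37 (-0.81, with its other probe at 0.22), Rspry1 (-0.83, detected on 1 of 3 knockout arrays) and Asf1a (-0.85), each with an adjusted p of 0.1, and Ppp4r3b (-0.77, adjusted p = 0.12). With 1 group undetected, there followed C1qdc1 (at least 1.19-fold lower, adjusted p = 0.1) and Gzmd (at least 1.27-fold higher, adjusted p = 0.13). Otx2 was at 8.58 ± 0.19 in control and 6.14 ± 1.45 in knockout posterior arrays (SD, n = 3), a change of -2.44 (SE 0.49, adjusted p = 0.14). Knockout posterior replicate 2, the array with the weakest signal, did not detect Otx2 (4.54, against 7.38 and 6.49), and without knockout posterior replicate 2 the change was -1.65.

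By list, camera called 8 in the posterior region, none of which held with an estimated correlation, and no member of any list passed when adjusted over all genes. Adjusted over the list alone, 6 of 15 forebrain and 5 of 17 pluripotency genes were lower, 3 of 16 node and notochord genes higher, and 1 each of the Hox and paraxial mesoderm genes higher. Hox genes had a median of 0.32 (adjusted p = 0.14 with an estimated correlation) and extraembryonic and lateral mesoderm of 0.24 (adjusted p = 0.21 with an estimated correlation). Medians were also positive for paraxial mesoderm 0.21 (adjusted p = 0.14 with an estimated correlation), cardiac and anterior mesoderm 0.21 (adjusted p = 0.29 with an estimated correlation), Wnt targets 0.1 (adjusted p = 0.14 with an estimated correlation) and node and notochord 0.07 (adjusted p = 0.36 with an estimated correlation). The lower lists were epiblast pluripotency at -0.44 (adjusted p = 0.21 with an estimated correlation) and forebrain at -0.39 (adjusted p = 0.14 with an estimated correlation). Under median scaling, which moved the median of all genes by -0.68, the medians of all 6 higher lists turned negative. Of the 36 genes higher in the anterior knockout arrays, 27 were also higher in the posterior ones, with a median of 0.21 against 1.11. Of the 20 lower genes 12 were also lower, with a median of -0.11 against -1.11. All of these genes were chosen on the anterior arrays, which inflates their anterior medians, so the sizes cannot be compared between the regions. The median posterior change of all genes was -0.022. Across all genes, which are not independent replicates, the anterior and posterior genotype changes had a correlation of 0.24.

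The count of 0 by limma in the posterior region stood beside 1104 genes with an unadjusted p under 0.05. Other settings gave up to 13 genes: 4 without background correction, 8 with an offset of 50, 3 with cyclic loess, 4 from the series matrix, 1 with the stricter filter, 6 with trended and robust variances, 13 with array weights and 2 with median scaling over the probes detected on all arrays. Without knockout posterior replicate 1 there were 21 genes (3 higher and 18 lower), without knockout anterior replicate 2 there were 2, and without control anterior replicate 1 or 3 there was 1. Camera called 3 lists without knockout posterior replicate 1 and 4 without knockout posterior replicate 3.

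Averaged over both regions, the retinoic acid enzyme gene Aldh1a2 rose by 1.32 (SE 0.18, adjusted p = 0.0067) and the Wnt target Sp5 by 0.79 (SE 0.08, adjusted p = 0.0019). Otx2 fell by 1.77 (SE 0.35, adjusted p = 0.045), Fgf5, an epiblast growth factor, fell by 1.18 (SE 0.23, adjusted p = 0.043) and Slc7a3 fell by 1.04 (SE 0.11, adjusted p = 0.0019), with its other probe at 0.14. Without knockout posterior replicate 2, which did not detect it, Otx2 changed by -1.38 (adjusted p = 0.0032). Also higher were Lypd2 (1.27), Myl2 (1.19), Igfbpl1 (1.15), Wnt2 (1), Gfra3 (0.96), Gpx2 (0.84), Crabp1 (0.76), Tcf21 (0.71), Pdlim4 (0.7) and Rasgrp3 (0.65). Also lower were Sox2 (-1.1, its other probe -0.28), Fzd5 (-0.99, its other probe -0.44), the netrin receptor gene Unc5b (-0.98), Pou3f1 (-0.97), the forebrain gene Otx1 (-0.97), Gatad2b (-0.74), Arid5b (-0.72), Kif21a (-0.71) and Gkap1 (-0.67, with its other probe at 0.14). Calls were lost most often, of 25 other settings, for Gkap1 (16), Gatad2b (15), Otx2 (14), Otx1 (14), Tcf21 (14), Crabp1 (13) and Kif21a (13). In all 28 genes were higher and 29 lower (57), of which 29 were among the 56 of the anterior region, and 1377 had an unadjusted p under 0.05. Median scaling gave 0 genes, with a shift of -0.44 in the median of all genes, median scaling over the probes detected on all arrays 9, Xist as a covariate 12, and array weights 624. An offset of 50 gave 111, the series matrix 108, and no background correction and trended variances 97 each. Without 1 array the count was 21, 19, 29, 33, 25, 32, 35, 121, 35 or 31 (control anterior replicates 1 and 2, control posterior replicates 1, 2 and 3, knockout anterior replicates 1 and 3, and knockout posterior replicates 1, 2 and 3).

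Whether the genotype effect differed between the regions was tested by the interaction. Rhbg was the 1 gene past the threshold, with a change of -1.44 (SE 0.16, adjusted p = 0.01). Its level was 4.74 ± 0.1 in control anterior (detected on 1 of 3 arrays), 6.13 ± 0.09 in knockout anterior, 6.58 ± 0.08 in control posterior and 6.53 ± 0.08 in knockout posterior arrays (SD, n = 3). The other genes with the 10 smallest p-values did not pass. They were Shisa2 (1.47, its other probe 0.23, adjusted p = 0.11), Hdc (1.84, its other probe 0.4), Gsc (1.52), Fst (-1.46) and Foxc2 (-1.87), each with an adjusted p of 0.15, Odf3b and Rhox9, also with 0.15 but without a size because no knockout anterior array detected them, and Fzd5 (1.21) and Hoxb1 (-1.49), each with 0.17. Of the lists, 12 passed camera, and 4 of them held with an estimated correlation. They were paraxial mesoderm (median -0.69, adjusted p = 0.0068 with an estimated correlation), Wnt targets (-0.34, 0.016), primitive streak (-0.52, 0.016) and midbrain and hindbrain (-0.37, 0.024). Other splits of the arrays did not exclude chance for the counts of genes and lists: 12 of 100 splits, the real one included, gave at least 1 gene and 5 of 100 gave at least 12 lists. Such splits can carry part of the genotype effect into the interaction, so these shares cannot decide on chance. At an unadjusted p under 0.05 there were 685 genes, where 556 would be expected. Rhbg did not pass without control posterior replicate 1, control posterior replicate 2 or knockout anterior replicate 1 (adjusted p of 0.062, 0.07 and 0.059). Its call was lost in 8 of 24 other settings without replicate blocks, and in 10 of 27 with them. Neither fixed replicate block left a gene past the threshold in the interaction. Over all alternatives the adjusted p of Rhbg ran from 0.0032 to 0.84 and its change from -1.92 to -0.46.

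The 2 regions themselves differed far more than the genotypes. In control arrays, the Wnt ligand of the primitive streak Wnt3a was higher in the posterior region by 6.3 (SE 0.24, adjusted p = 1e-08), the mesendoderm homeobox gene Mixl1 at least 19-fold (adjusted p = 1e-08), Tbx6 by 4.02 (SE 0.17, adjusted p = 2.6e-08) and the caudal homeobox gene Cdx1 by 3.92 (SE 0.41, adjusted p = 5e-05). In the anterior region Shisa2 was higher, with a change of -3.35 (SE 0.16, adjusted p = 3.4e-08). So were Cer1, a secreted antagonist of Nodal and BMP (-3.21, SE 0.22, adjusted p = 8.1e-07), the Wnt antagonist gene Sfrp1 (-2.78, SE 0.16, adjusted p = 1.6e-07), the atrial myosin light chain Myl7 (-2.75, SE 0.2, adjusted p = 1.7e-06) and Otx2 (-2.75, SE 0.49, adjusted p = 0.0045). Also higher posteriorly were Evx1 (3.76), Fst (3.57), Hoxb1 (3.54), Gal (3.34), Fzd10 (3.32), Nkx1-2 (3.28), Cdx2 (3.27) and Hoxd9 (3.26). Also lower posteriorly were Elf5 (at least 4.98-fold), Dppa4 (-2.73), Dnmt3l (-2.58), Foxd4 (-2.43), Fzd5 (-2.42), Wnt7b (-2.36) and Exosc2 (-2.34). Other probes changed less for Shisa2 (-1.45), Elf5 (-0.7), Fzd5 (-0.88) and Exosc2 (-0.24). Only some arrays of a group detected Hoxd9 (1 of 3 anterior), Dppa4 (2 of 3 posterior) and Wnt7b (1 of 3 posterior).

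Among the lists, 19 of 24 primitive streak genes rose toward the posterior region, 1 fell (Gsc) and 4 did not pass, with a median of 2.08. Wnt targets (17 of 25 rose, with Sp5 at 2.02, Axin2 at 1.8, Fgf8 at 2.12 and Lef1 at 1.48; 1 fell), Hox genes (14 of 22 rose, none fell), paraxial mesoderm (11 of 17 rose, none fell) and FGF/ERK signalling (9 of 20 rose, 1 fell) went the same way. Forebrain genes (9 of 15 fell, with Lhx5 at -2.19, detected on 1 of 3 posterior arrays, and Hesx1 at least 1.77-fold lower; 1 rose), anterior visceral endoderm and prechordal plate (8 of 11 fell, none rose) and definitive endoderm and foregut (7 of 15 fell, none rose) were lower posteriorly. These 8 lists passed camera with an estimated correlation too, with adjusted p-values from 3.3e-05 to 0.0084. The other 7 that passed with the preset value, then with an estimated correlation, were Wnt ligands and receptors (adjusted p = 0.079), midbrain and hindbrain (0.12), epiblast pluripotency (0.15), visceral endoderm (0.22), cardiac and anterior mesoderm (0.055), extraembryonic and lateral mesoderm (0.22) and primordial germ cells (0.12). Pou5f1 rose by 0.77 and Wnt3 was at least 1.28-fold higher (adjusted p of 0.033 and 0.042; the Wnt3 call was lost in 16 of 23 other settings), while Foxa2 (-0.44, adjusted p = 0.37) and Xist (-0.11, adjusted p = 0.98; other probes -0.11, 0.07 and 0.16) did not pass.

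In control arrays limma called 299 genes higher and 255 lower in the posterior region (554 genes), with 1882 at an unadjusted p under 0.05. Median scaling over all probes gave 48 higher and 26 lower. Median scaling over the probes detected on all arrays gave 254 higher and 131 lower, and the counts were 341 without control posterior replicate 2 and 368 without control anterior replicate 3.

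In the arrays labelled knockout the same axis was present. Wnt3a rose posteriorly by 5.34 (SE 0.24, adjusted p = 4.8e-08), Mixl1 at least 15.8-fold, Tbx4, a T-box gene of the allantois and hindlimb, at least 14.7-fold, Hoxd9 at least 11.3-fold and Hoxa5 at least 7.58-fold. Lower posteriorly were Otx2 (-4.1, SE 0.49, adjusted p = 0.00018), Cer1 (-3.35, SE 0.22, adjusted p = 9.6e-07), Myl7 (-3.2, SE 0.2, adjusted p = 6.7e-07) and Sfrp1 (-2.98, SE 0.16, adjusted p = 2.1e-07), and Tbx1 was at least 5.12-fold lower. Without knockout posterior replicate 2, which did not detect it, Otx2 changed by -3.3 (adjusted p = 4e-06). Further rises were Gal (3.5), Cdx1 (3.27), Evx1 (3.09), Fgf17 (3.05), Tbx6 (2.85), Hoxd4 (at least 5.89-fold) and Cdx4 (at least 5.67-fold). Further falls were Exosc2 (-2.54, with 1 other probe of opposite sign), the Iroquois genes Irx5 (-2.48) and Irx3 (-2.3), Tal2 (-2.19), Tcf15 (-2.04), Col2a1 (-1.9) and Pou3f1 (-1.88). The other probe changed less for Tbx4 (1.23) and Fgf17 (0.63). Only some arrays of a group detected Fgf17 (1 of 3 anterior), Tal2 and Col2a1 (2 of 3 posterior). In all 396 genes were higher and 480 lower (876), with 2599 at an unadjusted p under 0.05. Of these, 206 were also higher and 135 also lower in the control axis, where independent lists would share 10.6 and 11, and 0 went opposite ways. Across genes, which are not independent replicates, the correlation of the 2 axes was 0.7. The count was 544 without knockout anterior replicate 2, 542 without knockout anterior replicate 3 and 287 with only the groups compared. Median scaling over all probes gave 11 higher and 16 lower, with the median of all genes shifted by -0.52, and median scaling over the probes detected on all arrays gave 313 higher and 157 lower, with a shift of 0.16.

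**Figure D3:**
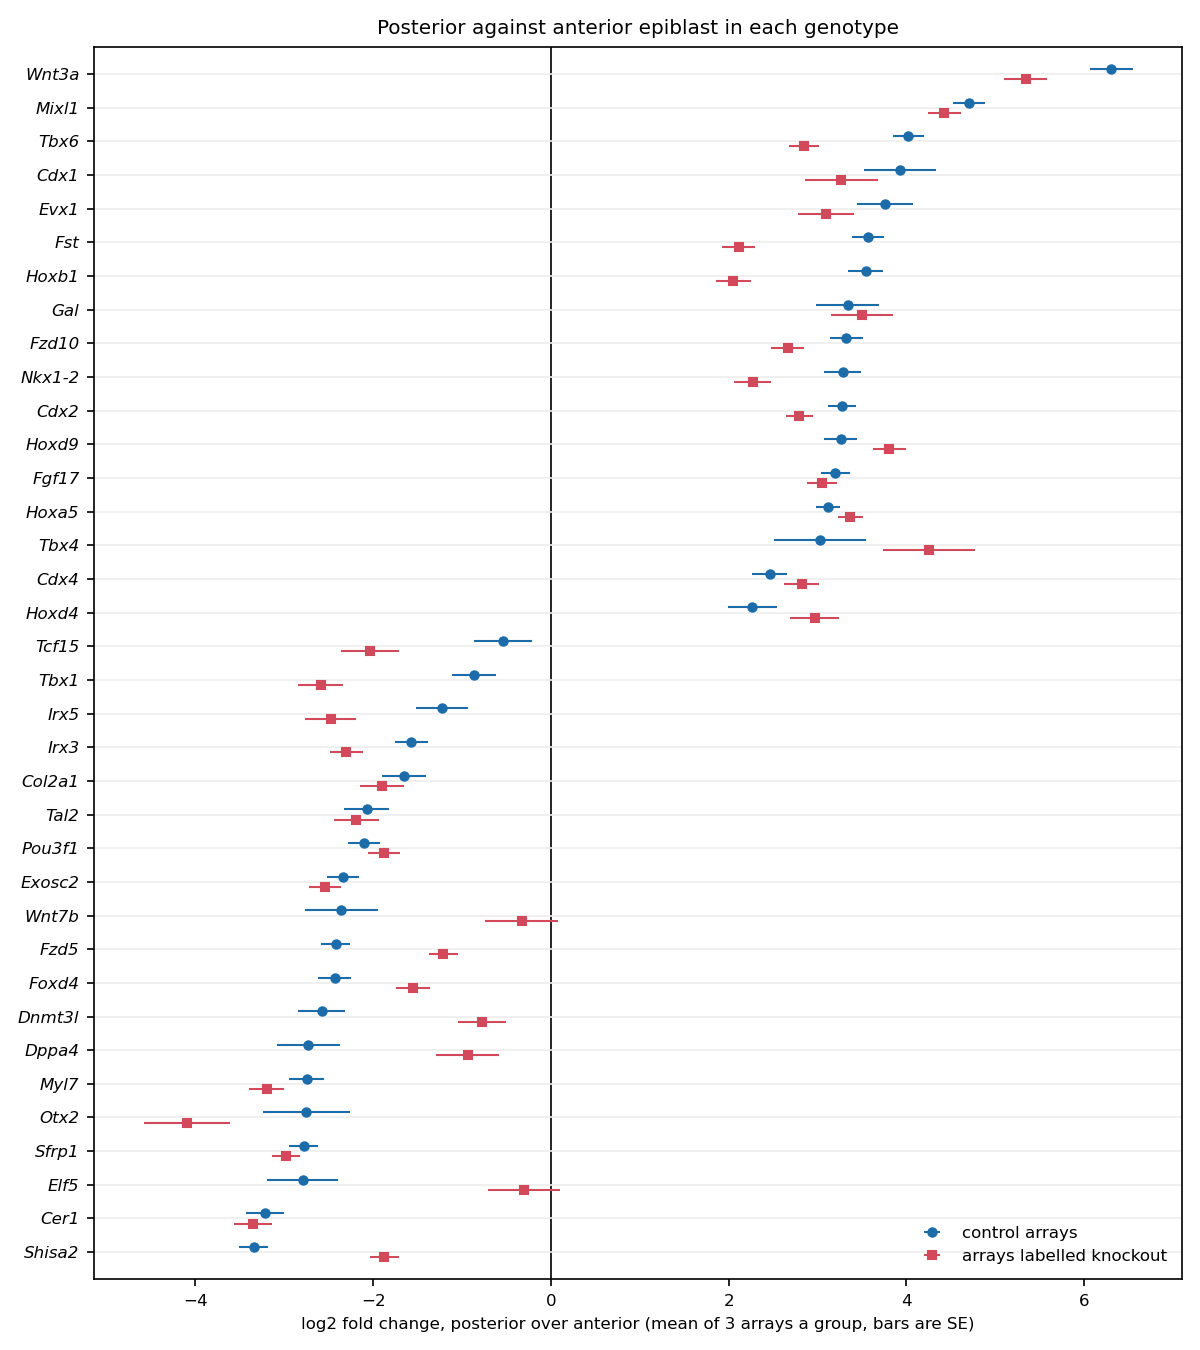
Log2 fold change, posterior over anterior (x axis, bars are SE), in control arrays and in arrays labelled knockout, for the genes named with the largest changes in either axis. Wnt3a changed by 6.3 in control and 5.34 in knockout arrays and Cer1 by -3.21 and -3.35; for genes undetected in 1 group the fitted change is drawn, not the lower bound.

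Along the control axis, the anterior knockout arrays lay 14.4% of the way from the anterior toward the posterior profile (SD 3.2 over 3 arrays, with 17.4%, 11% and 14.7%). Each control anterior array set against the other controls lay at 12.2%, -4.8% and -7.4%, so 1 control array fell within the range of the knockout arrays. A two-sided permutation of these scores between the groups gave p = 0.2, where 3 arrays against 3 cannot go below 0.1. The slopes were not computed anew for each permutation, and control arrays were scored against fewer controls than knockout arrays. The p-value is therefore only approximate. With the same arrays on both sides the slope was 21.3%, a value biased by the shared arrays. Without 1 array the share ran from 8.3% (control anterior replicate 2) to 23.4% (control posterior replicate 3), with 9.6% without control posterior replicate 1, and both median scalings gave 18.1%.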

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

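The tests of tissue share, boundary tissue, stage, swapped arrays, background, probe place and single arrays were chosen after the results were seen; the counts over other splits of the arrays were planned, except those that keep the arrays of a code together, which were added last. Groups of 3 arrays are too small for the search for single deviating samples, so none was made.

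The interaction of genotype and region passed its threshold for 1 gene and 12 lists, but other splits of the arrays did not exclude chance for either count. Rhbg had an interaction of -1.44, with a rise of 1.38 in the anterior region. Most control anterior arrays did not detect it, so these sizes are uncertain. In other settings the interaction ran from -1.92 to -0.46 and the anterior rise from 0.44 to 1.53. Lists with a lower effect in the posterior region had medians of -0.69 (paraxial and presomitic mesoderm), -0.52 (primitive streak), -0.39 (retinoic acid pathway), -0.37 (midbrain and hindbrain) and -0.34 (Wnt/beta-catenin targets). Lists with a higher effect in the posterior region had medians of 0.41 (node and notochord), 0.28 (extraembryonic ectoderm and trophoblast), 0.2 (extraembryonic and lateral mesoderm), 0.19 (immediate-early and stress genes), 0.19 (surface ectoderm and amnion) and 0.18 (definitive endoderm and foregut). The anterior visceral endoderm and prechordal plate list had a median of -0.14 but a mean of 0.21 and an upward test. With an estimated correlation the adjusted p was 0.19 for the retinoic acid pathway, 0.076 for node and notochord, extraembryonic ectoderm, immediate-early genes and surface ectoderm alike, 0.099 for extraembryonic and lateral mesoderm, and 0.27 for definitive endoderm and for anterior visceral endoderm.

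In the anterior arrays labelled knockout, several genes of the paraxial mesoderm and primitive streak were higher and several forebrain genes lower. The tables argue against a uniform share of posterior tissue in the anterior pieces: of 48 genes at least 4-fold higher in the posterior region, 26 departed by more than 2 SE from a mix at the median share of 8.97%, with implied shares of 0.928% for Wnt3a and 0.159% for Mixl1 against 53.4% for Meox1 and 58.3% for Arg1. Anterior pieces that held more tissue next to the boundary may contribute and cannot be told apart from an effect of the genotype, since 9 of the 36 genes that rose (Foxc2, Tbx1, Ripply2, Twist1, Meis1, Rasgrp3, Map3k10, Nolc1 and Pnliprp1) lay above both posterior groups and no profile of boundary tissue was analysed here. A more advanced stage stays open: in the posterior region the pluripotency list was lower and the Hox list higher, with 0.014 as the larger of the one-way p-values of fry, but with an estimated correlation both lost their camera call (0.21 and 0.14). Under median scaling the posterior Hox median became -0.34, though its camera call was kept. In the anterior region, where the pattern lay, the Hox median was 0.03. The genotype named by the design stays open beside these.

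The Dkk1 signal was as high in knockout as in control anterior arrays. A swap of single arrays between control and knockout in the anterior region is argued against, since each of the 6 anterior arrays lay on the side of its own genotype when scored on genes chosen without it; an exchange of the labels of all control and knockout arrays would not show in this test and stays open. A probe that reads only background is argued against as well, since it was detected on all 3 knockout anterior arrays and was at least 2.26-fold lower in the posterior region of the knockout (adjusted p = 4.5e-05). A probe outside the deleted part, or an allele that is still transcribed, could give the anterior change of 0.17 and stays open, because the array has 1 Dkk1 probe and the deleted part is not given in the sources used here.

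No gene passed in the posterior region, where the anterior region had 56. The smallest posterior adjusted p of limma was 0.0508, just over the threshold. At an unadjusted p under 0.05 there were 1104 genes in the posterior region and 1009 in the anterior region, where 556 would be expected in each. Without knockout posterior replicate 2, the array with the weak signal, the count stayed at 0. Leaving out an array also lowers the power, as in the anterior region, where 17 genes passed without control anterior replicate 2. The count of 0 therefore cannot decide whether the weak signal hides an effect. Knockout posterior replicate 1 may hide part of the effect, since 21 genes passed without it, but that count lay between the bounds set for this test and 1 array cannot be told apart from the spread of the group. A smaller genotype effect in the posterior region stays open as well, since chance was not excluded for the interaction.

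Other splits of the arrays were fitted in the same way. Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. The real splits gave 56 genes in the anterior region (highest other 0), 0 in the posterior region (0), 554 in the control axis (0) and 876 in the knockout axis (0), and 13 lists in the anterior region (highest other 6), 8 in the posterior region (4) and 15 in the control axis (12). For the average of both regions, 1 of 100 splits reached 57 genes, the real one, and the highest other gave 12. Chance is excluded by this only if the anterior and posterior arrays of a code are independent: kept together, they make 10 splits, too few for a share under 0.05 (57 genes, highest other 0). For the interaction 12 of 100 splits reached 1 gene and 5 of 100 reached 12 lists, with 57 genes and 14 lists as the highest others, so chance was not excluded. With the arrays of a code kept together, the interaction gave 1 gene (highest other 0) and 12 lists (highest other 3), again over 10 splits. The split with 57 genes exchanged the genotypes in 1 region only, which turns the interaction into the sum of both genotype effects. It therefore repeated the 57 genes called on average. With that split left out, 11 of 99 splits reached 1 gene and 5 of 99 reached 12 lists. Splits that exchange only some arrays of a region can also carry part of the genotype effect into the interaction. The shares over 100 or 99 splits therefore cannot decide on chance for the interaction, which was still not excluded.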

How the results depend on the processing

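Median scaling over the probes detected on all arrays and Xist as a covariate were chosen after the results were seen; all other alternatives were planned. Unless stated, the cause of a difference was not tested.

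Counts of genes moved by more than 1.5 times as follows. Without background correction there were 4 genes in the posterior region, 97 on average and 3 in the interaction. With an offset of 50 there were 93 anterior, 8 posterior, 111 on average and 3 in the interaction. Cyclic loess gave 3 posterior genes and 4 in the interaction. The series matrix gave 4 posterior, 108 on average and 4 in the interaction. With no filter 36 anterior genes passed, and with the filter at detection p under 0.01 on at least 6 arrays 1 posterior gene. With only the groups compared there were 27 anterior genes and 287 in the knockout axis. Trended and robust variances gave 87 anterior, 6 posterior, 97 on average and 12 in the interaction. Array weights gave 542 anterior, 13 posterior, 624 on average, 1607 in the control axis and 10 in the interaction, with control anterior replicate 2 at a weight of 5.71.

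Median scaling gave 0 anterior genes, 0 on average, 74 in the control axis, 27 in the knockout axis, 0 in the interaction and an axis share of 18.1%. It moved the median of all genes by -0.22 in the anterior and -0.68 in the posterior genotype comparison, -0.44 on average, -0.52 in the knockout axis and -0.44 in the interaction. Median scaling over the probes detected on all arrays gave 21 anterior genes, 2 posterior, 9 on average, 470 in the knockout axis, 0 in the interaction and an axis share of 18.1%. It moved the median of all genes by 0.16 in the posterior comparison, 0.13 on average and 0.16 in the knockout axis. With Xist as a covariate there were 18 anterior genes and 12 on average.

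Counts of lists moved in the posterior region to 3 with no filter, 5 with the stricter filter and 3 with median scaling over the probes detected on all arrays. With an estimated correlation there were 4 lists in the anterior region, 0 in the posterior region, 8 in the control axis and 4 in the interaction.

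When 1 array at a time was left out, the counts ran from 17 to 60 genes in the anterior region, 0 to 21 in the posterior region, 19 to 121 on average, 341 to 666 in the control axis, 542 to 885 in the knockout axis and 0 to 4 in the interaction. The axis share ran from 8.3% to 23.4%. Lists past the threshold ran from 10 to 14 in the anterior region, 3 to 9 in the posterior region, 12 to 16 in the control axis and 10 to 13 in the interaction. Of the lists in the anterior region, the forebrain, paraxial mesoderm, primitive streak and Wnt target lists kept their calls in every setting.

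Named genes that had passed kept their sign in every setting. With median scaling the anterior changes became -0.09 for Dkk1, 0 for Cer1 and -0.15 for Foxa2, and the medians of the 6 higher lists in the posterior region became -0.59 (Wnt/beta-catenin target genes list), -0.65 (paraxial mesoderm), -0.55 (node), -0.47 (extraembryonic and lateral mesoderm), -0.35 (cardiac) and -0.34 (Hox genes). Relative to other genes, the direction of the test reversed only for the Wnt targets (adjusted p = 0.78), and only Hox and cardiac kept their calls. The same scaling turned the medians of midbrain and hindbrain in the anterior region (-0.02) and of 5 interaction lists: surface ectoderm (-0.3), definitive endoderm (-0.26), extraembryonic and lateral mesoderm (-0.25), extraembryonic ectoderm (-0.1) and immediate-early genes (-0.05). The interaction median of anterior visceral endoderm became 0.29 with cyclic loess and 0.33 with median scaling over probes detected on all arrays, which also turned the anterior node median to 0.09. Leaving out 1 array turned this interaction median to 0.02 or 0.05 and the midbrain and hindbrain median in the control axis to -0.05 or -0.09. Of genes with an undetected group, for which only the sign of the fitted change is meant, with median scaling over probes detected on all arrays the posterior changes became 0.43 for Dkk1 and 0.13 for C1qdc1. With the Xist covariate the anterior change of Wnt3, undetected in both groups, became -0.08, and without 1 array it ran from -0.05 to 0.17. In the control axis the change of Xist became 0 with the mean of all detected probes and 2.33 with array weights, and without 1 array it ran from -1.57 to 1.24.

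Whether arrays of the same number form pairs was checked. Correlations of the deviations of anterior and posterior arrays of the same code were 0.06, 0.21 and 0.22 in control and -0.03, -0.11 and 0.05 in knockout, and 2 of 6 arrays fitted best with their own code, so the arrays were treated as unpaired. The levels of Xist and Eif2s3y, given below, did match by code. The fits of the average, the interaction and both axes may therefore treat arrays of the same embryos as independent. With the replicate number as a fixed block 1 posterior gene and 0 interaction genes passed, with genotype and number as a fixed block 0 interaction genes, and with a random block (correlation 0.031) 1 posterior gene.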

Other observations

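The tests of shared embryos were chosen after the levels of Xist and Eif2s3y were seen; the tests of linked variants and of the sex chromosomes were planned.

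Genes of the extraembryonic ectoderm differed between the regions of the control epiblast in both directions. Of 20 genes measured in that list, 6 were lower in the posterior region, among them Elf5 and Wnt7b, a transcription factor and a ligand known from that tissue, and 4 were higher, among them Cdx2, which the primitive streak list also holds. In the knockout axis 1 was lower and 6 were higher. The interaction did not pass for Elf5 or Wnt7b, and for the list it did not pass with an estimated correlation (adjusted p = 0.076). A difference between the genotypes in this axis was therefore not shown. Within the anterior region the list was lower in knockout arrays by camera (adjusted p = 0.0032), but not with an estimated correlation (adjusted p = 0.13). Adjusted over the list alone, 7 of its 20 genes were lower there and 2 higher.

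Xist, expressed from the inactive X chromosome, was not detected in control replicate 2 of either region (4.36 and 4.45), and the Y-linked Eif2s3y was not detected in knockout replicate 3 of either region (4.37 and 4.32). All other arrays detected both, which a pool of embryos of both sexes would give. Levels of these genes matched between anterior and posterior arrays of the same code better than in any other of the 36 pairings within genotype, with an exact one-sided p of 0.0278, the smallest these pairings can give. This p-value restates the match that prompted the test and is not separate evidence. Arrays of the same code may come from the same embryos or pool.

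Genes that differed between the genotypes, in the anterior region or on average, numbered 84. Of the 200 tested genes nearest to Dkk1, 100 on either side, 2 were among them (Gna14 and Nolc1; Fisher's exact p = 0.66), so variants carried along with the targeted locus were neither shown nor excluded and could still account for these 2. Of 343 genes on the X and Y chromosomes, 3 were among them (Chst7, Rhox9 and Slc7a3; Fisher's exact p = 0.75), so the test could not decide on the sex of the embryos. With Xist as a covariate, chosen after the data were seen, 18 genes passed in the anterior region instead of 56 and 12 on average instead of 57. The anterior changes of Sp5 (1.18) and Fzd5 (-1.62) kept their size and 13 anterior lists still passed. These are 2 genes with small adjusted p-values, and the genes that lost their call were not examined as a set. Control anterior replicate 2, the only anterior array that did not detect Xist, also gave the lowest anterior count when left out (17). Sex was therefore neither shown nor excluded as a cause of the lower counts.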
